A study of Mus musculus with 12 samples.

How the data were processed

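Small RNA libraries were made by the authors from the livers of 8-week-old male and female CD1 mice, 6 of each sex, with a commercial small RNA library kit from RNA extracted with a phenol-based reagent, per the labels' protocols. The submitters' processing notes name Trim Galore, Bowtie2, bedtools and edgeR and the genome build mm9, with no versions and no order. Aligner settings, the release of the microRNA annotation, filters and the use of strand in counting are not given in the sources used here.

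The deposited table holds whole-number read counts made by the authors for each of 2044 mature microRNA loci in each of the 12 livers, not normalized, with replicates kept separate. Its coordinates are on mm9 and carry no strand. The table also holds the authors' own comparison, per the file headers from edgeR: a log2 fold change of male over female, an average log2 CPM, and a p-value with its FDR, all deposited by the authors and used here only for the comparison with the calls made here. No other value columns were left unused.

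Loci of the same mature name were summed, since counts of 78 names stand at several loci. This gave 1906 names. For 25 pairs of such copies with at least 300 counts each, the split between the copies had a median chi-square per degree of freedom of 1.28 over the livers, and 17 were under 3. Most splits were thus nearly constant over the livers, as a random assignment of shared reads would give. A fixed unequal ratio would pass too, as for miR-128-3p with 4823 and 2008 counts (2.36). 40 pairs of loci with different names overlap in position. Of the 26 pairs with at least 100 counts, 24 differed by under 1%, as counting without regard to strand would give, although the use of strand is not stated. Values of such names cannot be told apart from those of their partners. The member of each pair with fewer counts held 3.12% of all counts.

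Libraries were scaled by the trimmed mean of M values (TMM), and microRNAs were filtered with filterByExpr with the sex as group, which left 419 names. The sexes were compared in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest) on the counts, with no covariate, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Positive log2 fold changes mean higher in males. CPM values are scaled by TMM, and log2 CPM used a prior count of 2. A second criterion asked for at least 2-fold. The square root of the common dispersion, the biological coefficient of variation, was 0.252.

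The test, the samples, the lists and the rule for named microRNAs were fixed before the data were examined. Named are the 10 microRNAs with the largest fold change higher in males and the 10 higher in females among those past the threshold with a mean of at least 10 CPM, the 5 most abundant, all tested arms of miR-1948 and miR-802, and up to 4 members of each list, the 2 with the smallest p and the 2 most abundant. Names outside this rule are said to have been chosen after their values were seen. The lists were hepatocyte-abundant microRNAs, microRNAs of lipid and cholesterol metabolism, the let-7, miR-29, miR-30 and miR-17-92 families, X-linked clusters, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 intron cluster, markers of immune, erythroid and endothelial cells, of stellate cells, fibroblasts and smooth muscle, of biliary and other epithelia, of striated muscle, pancreas, nervous system and gonad, and the microRNAs named in the study's publication. A member is any mature arm of a listed name, and members can stand in several lists. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, and with an estimated correlation) and with fry, adjusted over the lists; the pancreas and gonad lists had fewer and were only counted.

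X-linked and other microRNAs were compared by Fisher's exact test, two-sided, leaving out 3 names with loci both on X and on an autosome. The arms of a hairpin were compared by correlation across hairpins with 100000 permutations and by limma on the log2 ratio of the arms per liver. Shares of counts and numbers of detected microRNAs, with at least 10 counts, were compared by an exact two-sided permutation test over all 924 arrangements of the livers, adjusted over the 6 measures. Host genes came from GENCODE annotation of a later build, matched by microRNA gene name for 100 of 107 microRNAs; no coordinates of that build were used.

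The comparison was tested on simulated data with 200 of 419 microRNAs changed. Depths were the real ones, but every microRNA was drawn independently with the same dispersion, near the real common dispersion. It recovered 44.8% of changes of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold, with 1.23% false among its calls and 0 calls when nothing was changed. Differences of 1.5-fold were thus often missed at that spread. The real spread differs between microRNAs and livers, so these rates need not hold for the real data. Of 17 simulated lists only the 1 that was raised was called, and of 124 simulated hairpins all 10 with a change in a single arm were called, with 2 called wrongly. Because simulated members were independent, this could not show how the list test behaves with correlated members. In the real miR-29 family the estimated correlation was 0.295.

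Alternatives were other scalings (DESeq2 size factors, total counts only, upper quartile), other tests (DESeq2 1.42.0, edgeR's likelihood ratio and exact tests, limma-voom, robust dispersion), no filter and a filter at a mean of 10 CPM, the replicate number as a block, loci as deposited, the most abundant microRNA left out, thinning to the smallest library, and each library left out. Added after the data were seen were overlapping loci counted once and male 1 and male 4 left out together, and the runs of the lists, arms and X-linked shares with each library left out and under the other scalings.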

Results

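Small RNA was sequenced from the livers of 8-week-old male and female CD1 mice, an outbred laboratory stock, to find microRNAs whose abundance differs between the sexes. Each sex had 6 livers and each liver gave 1 library. The labels call the libraries replicates of a sex and do not say how the animals were housed or handled in batches, so the p-values measure the spread between these livers. Total microRNA counts per liver lay between 2953955 and 5516430. The mean was 3993890 ± 955946 in males (SD, n = 6) and 4020680 ± 686165 in females (SD, n = 6), with no detectable difference (exact two-sided permutation test, p = 0.961). At this depth a floor of 3 counts corresponded to between 0.544 and 1.02 CPM, which covers counting error only. CPM are counts scaled to a common library size, and this floor was scaled by total counts alone, without TMM. Of 1906 mature microRNA names in the table, 1292 had at least 1 count. The 419 names that passed the filter on low counts held 99.97% of all counts and were tested. No pair of libraries of the same sex agreed within sampling noise, as a library deposited under 2 names would, with a chi-square per degree of freedom of 21.0 in the closest pair, female 4 and female 5, and 415 in the most distant, male 1 and male 2.

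Male and female livers differed in 71 of the 419 tested microRNAs, 35 higher in males and 36 higher in females. They included both arms of miR-1948, miR-455 and miR-21a, higher in males, and of miR-802, miR-674 and miR-335, higher in females. Most differences were modest: 51 of the 71 were under 2-fold, and the median fold was 1.56 among those higher in males and 1.44 among those higher in females. The 20 of at least 2-fold comprised 12 higher in males and 8 higher in females. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Without adjustment, 123 microRNAs passed a p of 0.05, where chance gives 21. In 34 tested microRNAs the values of the sexes did not overlap at all, where chance gives 0.216% of names, or 0.907 names. The 71 names carried 70 distinct signals, because miR-374b-5p and miR-374c-3p are read from overlapping loci and had identical counts. The count was 47 without male 3, the only single liver whose omission moved it by more than 1.5 times, and the number of at least 2-fold fell to 12 without male 6. It was 10 where only microRNAs with a mean of at least 10 CPM were tested. Scaling by total counts alone called 26 higher in males and 58 higher in females, or 31.0% higher in males against 49.3% here. That scaling moved the median log2 fold change of all tested microRNAs from -0.02 to -0.12. Male 1 stood apart from the other males, with a median absolute log2 deviation from them of 0.320. By this measure male 4 did not stand apart, with a deviation of 0.161, below that of male 6 (0.268) and male 2 (0.192). It was unusual in single microRNAs and in its position between the sexes. On the microRNAs called without it, male 4 lay at 0.612 of the way from the female mean to the mean of the other males. That was the lowest position of any male, where male 1 lay at 0.666. Without both male 1 and male 4 the count was 84, with 24 of at least 2-fold, a check chosen after the data were seen. The count was 82 without male 1 alone and 69 without male 4 alone.

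Both arms of miR-1948, a microRNA that the linked publication, as remembered, followed up, were higher in males. miR-1948-5p (mm9 chromosome 18, 12873334 to 12873354, in an intron of Ttc39c) averaged 357 ± 98.1 CPM in males and 56.1 ± 7.61 CPM in females (SD, n = 6 each). Its log2 fold change was 2.67 with a standard error of 0.17, or 6.36-fold (adjusted p = 3.24e-07), and all 6 male livers lay above every female liver. The opposite arm, miR-1948-3p (12873371 to 12873392), was much rarer at 6.57 ± 1.55 CPM against 1.06 ± 0.531 CPM. It differed by nearly the same amount, with a log2 fold change of 2.61 (adjusted p = 0.00012, all 6 males above every female). The female values of miR-1948-3p, 0.476 to 1.96 CPM, lay near the floor of 3 counts, so the size of its difference is less certain. miR-3084-3p is read from 2 loci on mm9 chromosome 19, 25016730 to 25016750 and 60850237 to 60850257, with a host gene known for 1 of them, in an intron of Cbwd1. Its 2 copies had near-equal counts (787 and 747 in all), so reads were not specific to a copy. It had 55.5 ± 32.7 CPM in males and 12.5 ± 5.23 CPM in females, a log2 fold change of 2.16 (adjusted p = 0.00315, 5 of 6 males above every female). miR-592-5p (mm9 chromosome 6, 27886711 to 27886733, in an exon of Grm8) varied strongly within each sex, with 199 ± 116 CPM in males and 40.5 ± 23.7 CPM in females. Its log2 fold change of 2.30 had a standard error of 0.70 (adjusted p = 0.0418). Male 4, at 15.5 CPM, was below 5 of the 6 females, and the remaining 5 males lay above every female.

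Both arms of miR-455, which lies in an intron of Col27a1 on mm9 chromosome 4, were also higher in males. miR-455-5p (62917901 to 62917922) had 865 ± 233 CPM against 355 ± 58.7 CPM, a log2 fold change of 1.29 (adjusted p = 0.000768, 5 of 6 males above every female, the exception being male 1 at 403 CPM). miR-455-3p (62917938 to 62917958) had 596 ± 92.2 CPM against 273 ± 59.6 CPM, a log2 fold change of 1.13 (adjusted p = 0.000398, 6 of 6 males above every female). miR-21a-5p, a microRNA raised in many injured and proliferating tissues, was the second most abundant of all. It lies in an exon of Vmp1 (mm9 chromosome 11, 86397622 to 86397643) and had 170965 ± 34948 CPM in males against 82215 ± 8834 CPM in females. The log2 fold change was 1.06, or 2.08-fold (standard error 0.12, adjusted p = 0.000153), with all 6 males above every female. The rarer arm miR-21a-3p showed a log2 fold change of 1.02 (adjusted p = 0.021, 5 of 6 males above every female). The list of the 10 largest rises in males, among microRNAs with a mean of at least 10 CPM, was completed by miR-149-5p (log2 fold change 1.01, adjusted p = 0.0232, 5 of 6), miR-221-5p (0.95, adjusted p = 0.00343, 5 of 6) and miR-677-5p (0.89, adjusted p = 0.00265, 6 of 6), with the number of males above every female given last. miR-101b-5p, with 7.73 ± 3.01 CPM in males and 1.65 ± 0.56 CPM in females, was below the abundance minimum for naming and was chosen after its values were seen. Its log2 fold change was 2.19 (adjusted p = 0.000557, 6 of 6 males above every female).

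Both arms of miR-802, which is raised in livers of obese mice, and of miR-674 were higher in females. miR-802-5p (mm9 chromosome 16, 93369982 to 93370003, between annotated genes) averaged 241 ± 31.5 CPM in females and 105 ± 27.2 CPM in males (SD, n = 6 each). Its log2 fold change was -1.20, or 2.29-fold (standard error 0.16, adjusted p = 0.000398), and all 6 female livers lay above every male liver. miR-802-3p (93370020 to 93370041) had a log2 fold change of -1.08 (adjusted p = 0.00135, 6 of 6 females above every male). miR-674-3p (mm9 chromosome 2, 117010922 to 117010943, between annotated genes) had 60.6 ± 4.72 CPM in females and 29.0 ± 8.93 CPM in males, a log2 fold change of -1.06 (adjusted p = 0.000974, 6 of 6), and miR-674-5p -0.77 (adjusted p = 0.00898, 6 of 6). Both arms of miR-335, which lies in an intron of the imprinted gene Mest, were higher in females. miR-335-3p changed by -0.85 (adjusted p = 0.00343, 5 of 6 females above every male) and miR-335-5p by -0.75 (adjusted p = 0.0196, 4 of 6). The other members of the 10 largest rises in females, with the same minimum, were miR-6239 (-0.94, adjusted p = 0.0351, 3 of 6), miR-6406 (-0.84, adjusted p = 0.0212, 2 of 6), miR-218-5p (-0.83, adjusted p = 0.0449, 2 of 6) and miR-34a-5p (-0.77, adjusted p = 0.0294, 5 of 6), the last a transcriptional target of p53. miR-296-5p, below the abundance minimum and chosen after its values were seen, had 7.01 ± 0.876 CPM in females and 1.96 ± 1.14 CPM in males, with a log2 fold change of -1.80 (adjusted p = 0.000974, 6 of 6 females above every male).

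**Figure D1:**
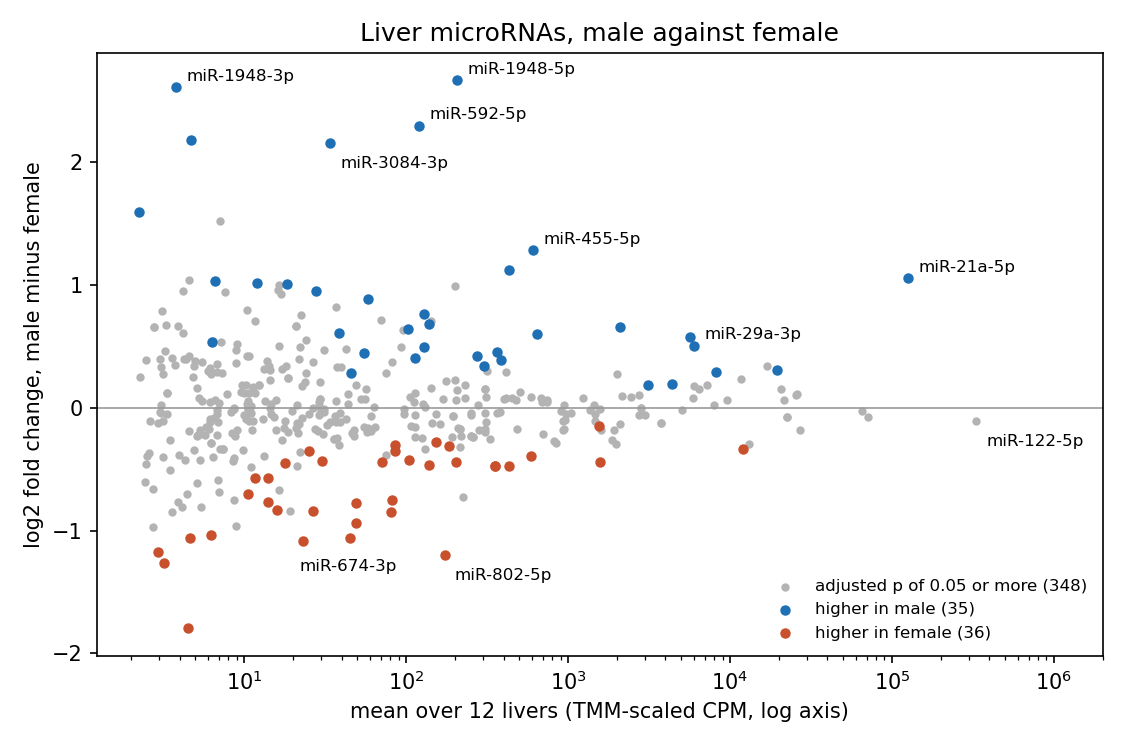
Log2 fold change between male and female livers (vertical axis, positive values higher in males) against mean abundance over the 12 livers in TMM-scaled CPM (log axis) for the 419 tested microRNAs. Blue points mark the 35 microRNAs higher in males and orange points the 36 higher in females at an adjusted p under 0.05; miR-1948-5p lies highest at 2.67 and miR-21a-5p is the only microRNA above 100000 CPM with a call.

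**Figure D2:**
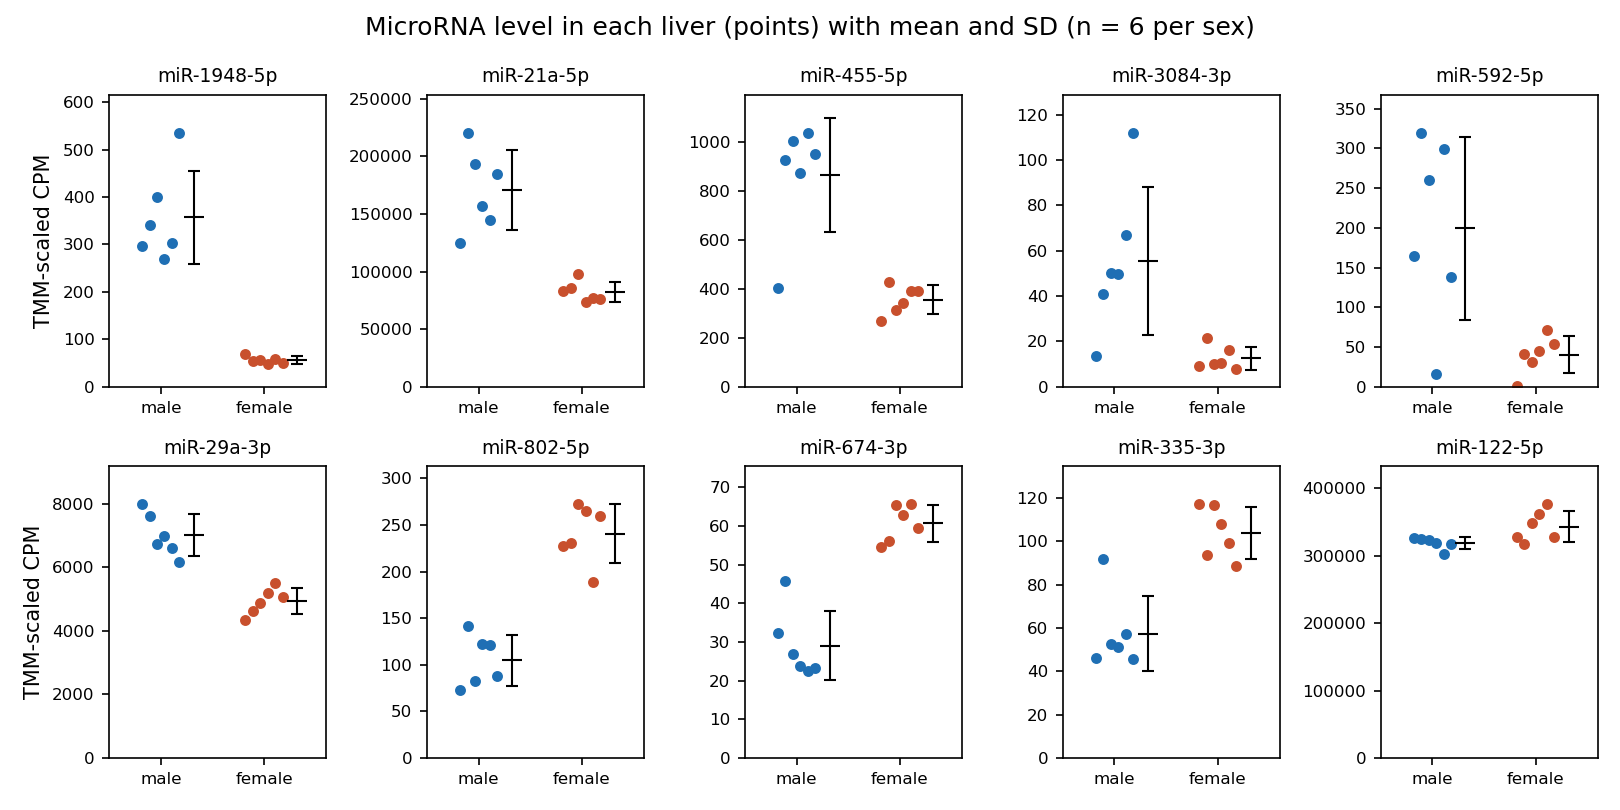
TMM-scaled CPM of 10 microRNAs in each of the 6 male (blue) and 6 female (orange) livers, on axes that start at 0, with the mean and SD drawn beside the points. For miR-1948-5p, miR-21a-5p, miR-29a-3p, miR-802-5p and miR-674-3p the sexes do not overlap, whereas miR-455-5p, miR-3084-3p, miR-592-5p, miR-335-3p and miR-122-5p have overlapping values.

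Of the 37 named microRNAs past the threshold, 23 passed with each liver left out in turn, among them both arms of miR-1948, miR-455, miR-21a, miR-802 and miR-674. Among the largest changes, miR-149-5p lost its call without female 2 (adjusted p = 0.0535) and miR-6406 without male 3 (adjusted p = 0.0541). Calls near the threshold were lost with several livers. The call of miR-34a-5p was lost without any of male 2, 3 or 5 or female 2, 5 or 6, with the highest adjusted p of 0.0713 without female 6. That of miR-592-5p was lost without any of male 2, 3 or 5 or female 2, 3, 4 or 6 (at most 0.0821, without female 3). That of miR-6239 was lost without any of male 2, 3, 5 or 6 or female 2, 3, 4 or 5 (at most 0.0735, without male 3). miR-218-5p kept its call only without male 4 or female 6 and otherwise reached 0.0861 without female 4.

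The composition of the libraries differed between the sexes in its most abundant members. miR-122-5p, the microRNA that dominates hepatocytes, took 30.8 ± 1.84% of counts in males and 35.6 ± 1.80% in females (SD, n = 6 each), a difference of -4.80 percentage points (exact two-sided permutation test, p = 0.00433, Benjamini-Hochberg adjusted over 6 library measures p = 0.00866). miR-21a-5p took 16.3 ± 2.48% against 8.52 ± 0.846% (exact permutation p = 0.00216, adjusted p = 0.00866), with all males above all females. After scaling by TMM, miR-122-5p itself did not pass the test, with a log2 fold change of -0.10 (standard error 0.04, adjusted p = 0.132). The same held for the other most abundant microRNAs, miR-148a-3p (-0.07, adjusted p = 0.54), miR-192-5p (-0.02, adjusted p = 0.82) and miR-194-5p (-0.18, adjusted p = 0.33). With miR-21a-5p left out of the total, the difference in the share of miR-122-5p was -2.11 percentage points (exact permutation p = 0.0541). The 10 most abundant microRNAs together held 74.1 ± 0.453% in males and 73.7 ± 0.594% in females (exact permutation p = 0.29). The number of microRNAs with at least 10 counts was 406 ± 15.0 in males and 423 ± 16.1 in females (exact permutation p = 0.104). With every library thinned to the smallest total, these numbers were 384 ± 6.59 and 397 ± 5.89 (difference -12.7, exact permutation p = 0.00433).

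Among 17 lists of related microRNAs that had at least 3 tested members, the miR-29 family and the hepatocyte-abundant list were higher in males by camera with a preset correlation. Neither passed with an estimated correlation, and 85 of 100 splits of the livers, the real one included, gave as many called lists, whichever these were. By fry, which asks only whether a set moves on balance in a single direction, the adjusted p was 0.00134 and 0.00368. The miR-29 family, which represses collagen and other matrix transcripts, had 6 tested members, all with positive log2 fold changes and a median of 0.44. 3 members rose in males, over all microRNAs and also adjusted over the list alone. These were miR-29b-3p (0.64, adjusted p = 0.000398, 6 of 6 males above every female), miR-29a-3p (0.51, adjusted p = 0.000667, 6 of 6; 7008 ± 669 CPM against 4929 ± 415 CPM) and miR-29c-3p (0.50, adjusted p = 0.0143, 5 of 6). The list's camera adjusted p was 0.00514, and the adjusted p was 0.338 with an estimated correlation. The hepatocyte-abundant list had 25 tested members, of which 8 rose and 2 fell in males over all microRNAs, and 9 and 2 adjusted over the list alone. Its median log2 fold change was 0.18 and its camera adjusted p 0.0207, with an adjusted p of 0.338 with an estimated correlation. The rising members were both arms of miR-21a, miR-455 and miR-22, miR-101b-5p and miR-365-3p, and those that fell were both arms of miR-802. Both arms of miR-22 and miR-365-3p were named after their values were seen. miR-22-3p, a microRNA expressed in many tissues, rose by 0.31 (adjusted p = 0.0216, 6 of 6 males above every female; 0.0535 without female 2). miR-22-5p (0.34, adjusted p = 0.0449) lost its call without any of male 1, 2, 3 or 4 or female 1, 2, 3, 4 or 6, with the highest adjusted p of 0.0936 without female 6. Of its most abundant members, miR-21a-5p rose, although it is also expressed in other liver cells, while miR-122-5p, miR-148a-3p and miR-192-5p were not called. The list's call was lost without male 2 (adjusted p = 0.114), where only microRNAs with a mean of at least 10 CPM were tested (0.153), with scaling by total counts alone (0.0807) and with libraries thinned to the smallest total (0.0564).

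The remaining families and clusters did not pass the camera test. Of 30 members of the lipid and cholesterol metabolism list, 3 rose and 1 fell in males, and 3 and 4 adjusted over the list alone (median 0.06, adjusted p = 0.472). The called members were both arms of miR-21a and miR-29a-3p, which rose, and miR-34a-5p, which fell; the first 3 are also members of the lists above. The let-7 family had 1 of 21 members higher in males, let-7f-2-3p (0.28, adjusted p = 0.0423), and 0 adjusted over the list alone (median 0.02, adjusted p = 0.683); its call was lost without any of male 1, 2, 3 or 6 or female 1, 2, 3, 4 or 6, with the highest adjusted p of 0.113 without female 6. The miR-30 family had 1 of 11 higher in males by both adjustments, miR-30e-5p (0.58, adjusted p = 0.00314, 5 of 6 males above every female), and a median of 0.08 (adjusted p = 0.26). The medians of these 3 lists turned negative when libraries were scaled by total counts alone. The miR-17-92 family, which promotes cell cycle entry, had 2 of 16 lower in males by both adjustments, miR-106b-5p (-0.46, adjusted p = 0.00584, 6 of 6 females above every male) and miR-17-3p (-0.35, adjusted p = 0.0216, 6 of 6; 0.052 without female 2). Its median was -0.12 (camera adjusted p = 0.196), while fry, which asks only whether a set moves on balance in a single direction, gave an adjusted p of 0.00857. The Dlk1-Dio3 imprinted cluster had 0 of 40 called by edgeR's test in either direction (median 0.25, camera adjusted p = 0.39), with levels that varied widely between livers. The list passed without male 2 (adjusted p = 0.0212, preset correlation), but its members had an estimated correlation of 0.742, with which the adjusted p in all livers was 0.836. In the Sfmbt2 intron cluster all 6 members had negative log2 fold changes (median -0.79, adjusted p = 0.0978). 1 fell in males, miR-669a-3p (-1.06, adjusted p = 0.0304), and 2 adjusted over the list alone, but its copies at several loci share reads. That call was lost without any of male 2, 3, 4 or 6 or female 2 or 6, with the highest adjusted p of 0.0734 without male 3, and the list passed without female 1, 3, 4 or 5 (adjusted p = 0.025, 0.0276, 0.0449 and 0.0169, preset correlation). With the estimated correlation of its members, 0.780, the adjusted p in all livers was 0.790. The list of the microRNAs that the study's publication named was chosen on these samples and is not independent evidence. All 4 of its members were called, both arms of miR-1948 higher and both arms of miR-802 lower in males, also adjusted over the list alone (median 0.77, camera adjusted p = 0.151, 0.0241 without male 6). With an estimated correlation the camera adjusted p of this list in all livers was 0.338.

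X-linked microRNAs were not called detectably more often than others in either direction. Of 43 tested X-linked microRNAs, 5 were higher in females, against 31 of 373 others (odds ratio 1.45, 95% interval 0.416 to 4.08, Fisher's exact test, p = 0.401). 5 of 43 were higher in males, against 30 of 373 (odds ratio 1.5, interval 0.43 to 4.24, exact p = 0.388; both 0.401 after adjustment over the pair). Of the 40 tested members of the X-linked clusters list, 4 rose and 4 fell in males by both adjustments (median -0.11, camera adjusted p = 0.391). Called or not, 30 had negative and 10 positive log2 fold changes, with a fry adjusted p of 0.0987. Those that rose were miR-221-5p, miR-221-3p (0.60, adjusted p = 0.00722, 5 of 6 males above every female), miR-222-3p (0.77, adjusted p = 0.00343, 6 of 6), which repress the cell cycle inhibitor p27, and the gonad-enriched miR-881-3p. The names that fell were miR-374b-5p and miR-374c-3p (both -0.47, adjusted p = 0.000768, from 1 set of counts, with 6 of 6 females above every male), miR-421-3p (-0.57, adjusted p = 0.0232) and miR-652-3p (-0.31, adjusted p = 0.0449), the last 2 with 5 of 6 females above every male. miR-421-3p lost its call without male 3, female 1 or female 2 (at most 0.0543, without male 3), and miR-652-3p kept it only without male 1, male 2 or female 5 (otherwise at most 0.0963, without female 3). miR-222-3p, miR-421-3p and miR-652-3p were named after their values were seen.

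Markers of other cells in whole liver showed few single differences, and the 5 lists of other liver cells (immune, erythroid, endothelial, stellate and biliary) all had a mean log2 fold change below 0, with an average of -0.146. Of 9 immune cell microRNAs, miR-142a-5p was lower in males (-0.47, adjusted p = 0.0256, 3 of 6 females above every male, also adjusted over the list alone; list median -0.15, camera adjusted p = 0.461). Its call was lost without male 3, male 6, female 1 or female 6, with at most 0.0632 without female 1. Of 10 microRNAs of stellate cells, fibroblasts and smooth muscle, both arms of miR-143 were lower in males, miR-143-3p by -0.34 (adjusted p = 0.0263) and miR-143-5p by -0.44 (adjusted p = 0.0273), also adjusted over the list alone (2 of 6 females above every male for each; list median -0.14, camera adjusted p = 0.26). miR-143-3p lost its call without male 2, 3 or 5 or female 1 or 2, and miR-143-5p without male 3 or 6 or female 1, 2 or 4, with at most 0.0632 and 0.0634, both without female 1. The erythroid list had 0 of 7 called by edgeR (median -0.23, camera adjusted p = 0.313), with miR-144-3p at -0.72 (adjusted p = 0.0531) and miR-451a at -0.01. The endothelial list had 0 of 4, read from 2 distinct signals (median -0.04, adjusted p = 0.719), with miR-126a-3p at -0.08, and the list of biliary and other epithelia 0 of 12 (median -0.17, adjusted p = 0.596). Striated muscle had 0 of 3 (median 0.67, adjusted p = 0.784). The only tested pancreas microRNA, miR-375-3p, was at 1.52 (adjusted p = 0.245). The muscle and pancreas values rested on male 4, which had 109 CPM of miR-1a-3p and 47.3 CPM of miR-375-3p, where the next highest liver had 32.5 and 5.44 CPM. Of 4 nervous system microRNAs, miR-129-5p was higher in males by both adjustments (0.54, adjusted p = 0.0415, 5 of 6 males above every female), but kept its call only without male 1, male 6 or female 5 (otherwise at most 0.09, without female 6); the list's camera adjusted p was 0.362 and its fry adjusted p 0.0284. Of 2 gonad microRNAs, the testis-enriched miR-881-3p was higher in males at 3.41 ± 0.649 against 1.07 ± 1.01 CPM (1.59, adjusted p = 0.036, by both adjustments, 5 of 6 males above every female), and its call was lost without any of male 3, 4, 5 or 6 or female 1, 5 or 6 (at most 0.0775, without male 3).

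**Figure D3:**
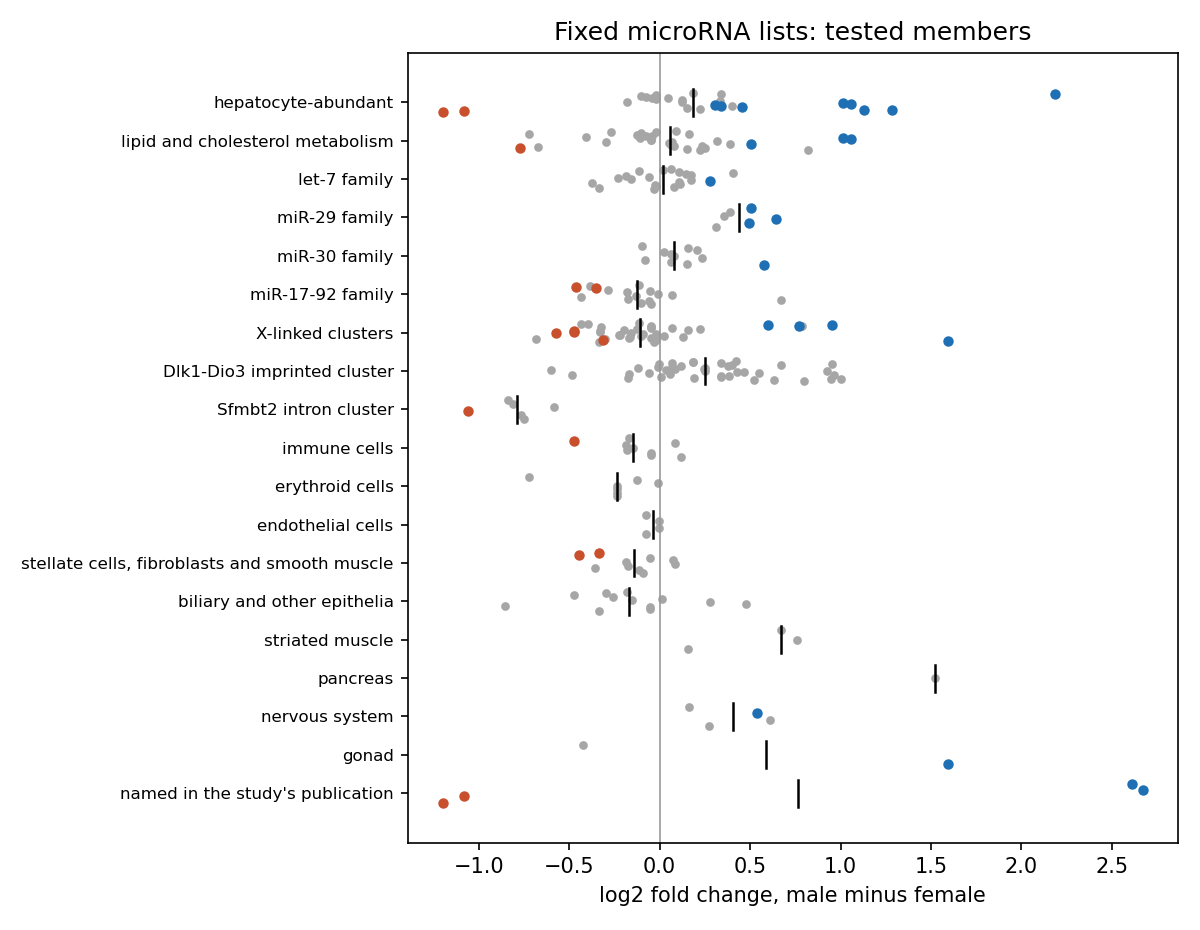
Log2 fold change between male and female livers of each tested member of the fixed microRNA lists (points; blue higher in males and orange higher in females at an adjusted p under 0.05, grey otherwise), with the median of each list as a vertical bar. The 6 members of the miR-29 family all lie above 0 around a median of 0.44, and the 6 of the Sfmbt2 intron cluster all lie below 0 around -0.79.

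The arms of a hairpin come from a common precursor. Across 124 hairpins with both arms tested, the log2 fold changes of the 5p and 3p arms correlated with Pearson's r = 0.73 and Spearman's rho = 0.60 (permutation p = 1e-05 for each, the smallest that the permutations can give), and r was 0.70 without the 2 hairpins farthest from the median. The permutations were across hairpins, which are not independent replicates. Over other splits of the 12 livers into groups of 6 the median r was 0.62 and the highest 0.81, and 5 of 100 splits, the real one included, had an r as high as the sexes, so the correlation is not specific to sex. Both arms were called in 12 hairpins, all 12 in the same direction, and a single arm in 24, where the other arm had the same sign in 21. Among the 124, 7 pairs of hairpins are read from overlapping loci, such as miR-374b and miR-374c; with each pair counted once, there were 117 hairpins with r = 0.74, 12 with both arms called, all in the same direction, and 23 with a single arm called, 20 of them with the same sign in the other arm. The ratio of the arms differed between the sexes in 3 hairpins by limma, which were named after their values were seen, and 24 passed an unadjusted p of 0.05. The 3 hairpins were miR-101b, where the 5p arm rose relative to the 3p arm in males by 1.6 on the log2 scale (adjusted p = 0.00902, 6 of 6 males above every female), miR-409 with -1.27 (adjusted p = 0.017, 5 of 6 males below every female) and miR-25 with 0.71 (adjusted p = 0.0298, 5 of 6 males above). The 5p arms of miR-101b and miR-25 were rare, with means of 4.69 and 3.27 CPM. By edgeR's test no single arm of miR-409 (5p and 3p adjusted p = 0.252 and 0.149) or miR-25 (0.0771 and 0.0917) was called. The number was 5 without male 1 or without male 4, 1 without female 2, female 3 or female 5, and 16 without both male 1 and male 4. It was 0 with libraries thinned to the smallest total and without a filter, and 1 where only microRNAs with a mean of at least 10 CPM were tested.

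**Figure D4:**
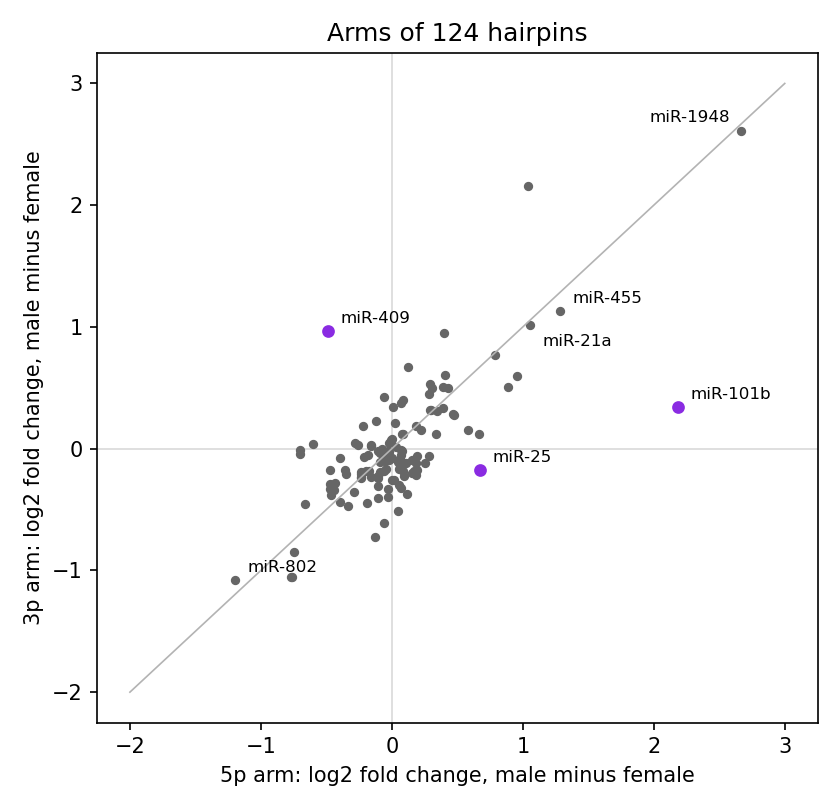
Log2 fold change between male and female livers of the 3p arm (vertical axis) against the 5p arm (horizontal axis) for 124 hairpins, with the line of equal change. miR-1948, miR-455, miR-21a and miR-802 lie near the line, and the 3 hairpins whose arm ratio differed between the sexes, miR-101b, miR-409 and miR-25, are drawn in purple.

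The calls here were compared with the authors' deposited table of the same comparison. That table held 48 loci with an FDR under 0.05, 32 higher in males and 16 higher in females, which carried 45 names. Of these, 42 were tested here, and 41 were called with the same sign. In turn, 30 names called here had no locus under 0.05 in the authors' deposited table. The authors' FDR values correspond to an adjustment over all 2044 loci, and those here were adjusted over 419 names with copies summed. The p-values differ too, so the counts and FDR values are not at a like threshold. The exception was miR-182-5p, chosen after its values were seen, which the authors' deposited table gives a log2 fold change of 1.04 and an FDR of 0.0404, and which here had 1.00 (adjusted p = 0.0542, 4 of 6 males above every female). The authors' deposited table gives miR-1948-5p 2.70 with an FDR of 1.56e-38 and miR-802-5p -1.16 with an FDR of 8.99e-07. The 3 names not tested here, named after their values were seen, were too rare for the filter. miR-383-5p had 1 count in all males and 24 in all females, miR-298-5p 11 and 45, and miR-871-3p 26 and 6. The authors' deposited table gives them log2 fold changes of -3.68, -1.80 and 2.17.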

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

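The tests of other cells in male 1 and in males, and all tests on male 4, were chosen only after the result was seen; the remaining tests were set beforehand. 156 groups of 6 values were examined for a liver far from the others of its sex, for which chance gives 7.8, and 22 values stood out, 10 of them in male 1 and 5 in male 4. CPM values are scaled by TMM.

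Male 1 lay apart from the other 5 males, low in miR-455-5p (403 CPM, nearest male 874), miR-30c-5p (9831), miR-30a-5p (11686, nearest 22055), miR-194-5p (16107, nearest 25309) and miR-192-5p (54819), and high in miR-6406 (35.3), miR-669c-5p (11.01), miR-499-5p (11.7), let-7f-5p (28161) and let-7g-5p (29941). The tables argue against a swap or a wrong sex label: on the microRNAs called without it, male 1 lay at 0.666 of the way from the female mean to the mean of the other males, above the highest female at 0.216. Fewer hepatocytes would raise all other cells alike: the hepatocyte-abundant list (-0.17 on the log2 scale against the other males) and the stellate (0.33) and erythroid (0.76) lists go with this, but biliary and other epithelia (-1.23), immune (-0.55) and endothelial cells (-0.33) fell by more than the SD of the other males and argue against it as the whole cause. Lower depth does not account for it either, since with all libraries thinned to the same total its median absolute log2 deviation from the other males was 0.333, where the highest of the others had 0.268. No biological explanation was tested, and a difference in RNA or library quality remains open.

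Male 4 carried high levels of microRNAs of other tissues, with 47.3 CPM of miR-375-3p, 109 CPM of miR-1a-3p and 19.4 CPM of miR-133a-3p, and it was also high in miR-143-5p (83.2 CPM) and miR-218-5p (19.9 CPM). miR-375-3p was 8.71-fold, miR-1a-3p 6.05-fold and miR-9-5p 6.14-fold above the highest other male. The position of male 4 between the female mean (0) and the mean of the other males (1) was 0.612, below every other male. That position used the microRNAs called without male 4. Pancreas tissue cannot be told apart from other sources: the sum of the other pancreas microRNAs was 1.19-fold above the highest other male, but none of them passed the filter on low counts (miR-217-5p had 8 counts in male 4), and they mark exocrine cells, so islets stay open too. RNA or reads of several other tissues may have contributed, and this cannot be told apart from a difference in the liver itself: 3 tested microRNAs exceeded 3 times the level of every other liver, miR-375-3p, miR-1a-3p and miR-1b-5p, the last from a locus that overlaps a miR-1a locus, while female 4 also had 22.4 CPM of miR-9-5p. No biological explanation was tested.

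Single values stood out in other livers. Male 2 was high in miR-335-3p (91.8 CPM) and low in the number of microRNAs with at least 10 counts after thinning (371). Male 6 was high in miR-494-3p (60.4 CPM) and miR-146b-5p (90.1 CPM). Female 5 was high in miR-221-5p (28.7 CPM) and miR-129-5p (6.38 CPM), and female 1 in miR-143-3p (15168 CPM).

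The lower share of miR-122-5p in males, 30.8% against 35.6% of counts, is consistent with counts taken by miR-21a-5p. With miR-21a-5p left out of the total the difference shrank from -4.80 to -2.11 percentage points and its exact permutation p was 0.0541, because the shares moved closer (36.8 ± 1.54% and 38.9 ± 1.73%) while their spread stayed similar. Fewer hepatocytes in male livers would raise the 5 lists of other liver cells, and no such rise was seen. Their mean log2 CPM per liver was 8.23 ± 0.0981 in males and 8.43 ± 0.115 in females (SD, n = 6 each, exact permutation p = 0.0152). All 5 lists had a mean log2 fold change below 0, although none passed the camera test. The comparison per liver was the third used for that explanation, all chosen after the values were seen, and the outcome depended on the choice. The mean log2 fold change over the lists, -0.146, lay beyond the SD over the lists (0.0790) but within that over their 42 single members (0.235). No verdict on fewer hepatocytes is therefore drawn. A lower level of miR-122-5p in male hepatocytes, as part of the sex difference that the design names, stays open and was not tested.

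Other splits of the 12 livers into groups of 6 were tested with 100 of the 462 splits. For the number of called microRNAs chance can be excluded: the sexes gave 71, the highest of the other splits 2, and 1 of the 100 splits, the real one, gave as many. The same holds for the number of at least 2-fold, 20 against at most 1 (1 of 100). For the hairpins whose arm ratio differed, the sexes gave 3 against at most 2 (1 of 100). The splits used the main settings only, and the sexes gave 0 such hairpins with thinning and without a filter. The splits therefore cannot exclude chance for these hairpins. Chance cannot be excluded for the number of lists called, 2 against up to 8 in other splits, with 85 of 100 giving as many. Nor can it be excluded for the correlation of the arms, 0.73 against up to 0.81, with 5 of 100 as high and a median of 0.62 over the other splits.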

How the results depend on the processing

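The runs with overlapping loci counted once, with male 1 and male 4 left out together, and those of the lists, arms and X-linked shares with single livers left out, other scalings, no filter or thinning, were chosen only after the result was seen. No result reversed. The number of called microRNAs was 71 and stayed within 1.5 times of that in every run except the one without male 3: DESeq2 size factors gave 70, total counts only 84 (26 higher in males, 58 in females), upper quartile 51, no filter 54, a mean of at least 10 CPM 63, loci as deposited 77, the most abundant microRNA left out 71, thinning 65, DESeq2 85, the likelihood ratio test 75, edgeR's exact test 72 and limma-voom 70. With single livers left out it ranged from 47 (without male 3) to 82 (without male 1), the cause of the lower number was not tested, and it was 74 with overlapping loci counted once and 84 without male 1 and male 4. The number of at least 2-fold, 20, ranged with single livers left out from 12 (without male 6) to 24 (without male 1). Of the other runs it was 15 with thinning, 28 with DESeq2 and 10 at a mean of at least 10 CPM, where fewer low microRNAs were tested; the cause of the change without male 6 was not tested.

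The number of lists called, 2, was 0 with an estimated correlation, 5 by fry, 5 without a filter, and 1 each with total counts only, at a mean of at least 10 CPM and with thinning; the cause was not tested. The Sfmbt2 intron cluster passed with the upper quartile (adjusted p = 0.0484) and, like the miR-30 family (0.0137), without a filter (0.000263), all with the preset correlation; with an estimated correlation (0.780 and 0.245) both had an adjusted p of 0.790. The number of hairpins with a sex difference in the arm ratio, 3, was 0 without a filter and with thinning, 1 at a mean of at least 10 CPM, between 1 (without female 2, 3 or 5) and 5 (without male 1 or male 4) with single livers left out, and 16 without male 1 and male 4, so this number depends on which livers enter; without a filter 422 hairpins were tested in place of 124. The difference in detected microRNAs passed the test only with thinning (-12.7, exact permutation p = 0.00433). The shares of counts, the correlation of the arms and the X-linked shares kept their side of the threshold in every run of this section, although the correlation was only 0.20 without a filter. The exception outside these runs was the share of miR-122-5p with miR-21a-5p left out of the total (exact permutation p = 0.0541). The sex difference of a detected rare microRNA is limited by depth: 3 counts were worth up to 1.02 CPM before TMM scaling.

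Of 2025 values of named microRNAs under alternatives, 1874 either kept direction and call or were called in neither run. Another 119 kept direction and lost the call, 32 gained it and 0 changed sign with a call. Where neither run gave a call, the sign was not compared and could change. The log2 fold change of miR-375-3p, for example, ranged from -0.248 to 1.75. Of the 37 named and called, 21 stayed called in every run. The replicate numbers shared by the sexes are not known to pair livers: the correlations of deviations between livers of the same number were 0.00, 0.27, -0.13, 0.00, -0.04 and 0.30, and for no number did both livers correlate best with each other. With the replicate number as a block, 48 microRNAs were called (26 higher in males, 22 in females), 17 of them at least 2-fold, and 46 of the 71 were also called. 8 named microRNAs lost their call, and no list, X-linked share or correlation of the arms changed its call. The test of the arm ratio did not take the block, so its number of hairpins could not change. Pseudocounts were not varied. The main test ran on counts, but the arm ratios and the list means per liver used log2 CPM with a prior count of 2. The effect of that prior on rare arms was not tested.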

Other observations

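The values below were chosen after they were seen, and no explanation of them was tested. Female 3 carried microRNAs that mark the exocrine pancreas: 57 counts of miR-217-5p, 20 of miR-216a-5p and 46 of miR-216b-5p, where the highest of the other livers, male 4, had 8, 7 and 11. All 3 were too rare for the filter. In CPM they were 13.6, 4.76 and 10.95 in female 3.

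The Dlk1-Dio3 imprinted cluster, a large cluster of maternally expressed microRNAs, varied widely between livers of a sex. Its mean log2 CPM was highest in male 6 at 4.78 and lowest in male 2 at 2.48, and the other 10 livers lay between 2.99 and 3.85. The estimated correlation between its members was 0.74. The Sfmbt2 intron cluster was likewise uneven among females, with a mean log2 CPM of 3.95 in female 2 and 3.63 in female 6 against 2.47 to 2.91 in the other 4 females, and 2.08 to 2.85 in the males.

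miR-592-5p had 3 counts in female 1 and between 131 and 301 in the other 5 females, and 64 counts in male 4 against 399 to 1551 in the other 5 males. miR-182-5p ranged from 92.3 CPM in male 1 to 429 CPM in male 4, while the females lay between 98.7 and 180 CPM. The split of miR-194-5p reads between its 2 loci varied over the livers, with a chi-square per degree of freedom of 232, and that of miR-26a-5p with 66.8. That is more than a random assignment of all reads would give. The statistic grows with depth, however, and the copies of miR-26a-5p had near-equal totals (521094 and 520725). How the reads were assigned to a copy was not tested.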
